A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

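RNA of 4 biological replicates of the translocant strain D10 Small and of a WT San I pool was hybridised to 4 two-colour yeast oligonucleotide arrays. Per the labels' protocols, 250 ng of total RNA was amplified from a T7 promoter primer and labelled with Cy3 for D10 Small and with Cy5 for the pool. The replicates are called biological in the labels, which do not say how the pool was made. Every array holds the same orientation of dyes, so a dye effect of a gene cannot be told apart from a difference between strains. D10 Small alone received kanamycin, so its effect cannot be told apart from that of the strain.

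The deposited scanner files give the spot intensity of each channel and its local background on a linear scale, per the file headers. They hold 45220 spots per array, of which 43792 belong to 6256 gene probes with 7 spots each and 153 are negative controls. The scanner software and its settings are not given in the sources used here. The files also hold a net log2 ratio, per the file headers, in which the pool's channel was rescaled to the other by a step that is not named. The authors' value table holds log2 ratios with medians of -0.000293, -0.00570, -0.00121 and 0.00265 on the 4 arrays. Its columns correlated with the ratios used here with r from 0.965 to 0.972 over genes and slopes from 1.17 to 1.26, which sets the direction as D10 Small over the pool and the centre as 0. How these values were normalised is not stated, and the reason for the steeper scale was not tested. The ratios used here were drawn toward 0 at dim genes by an offset of 50. They gave 359 genes at least 2-fold higher and 177 lower. Without background correction the counts were 538 and 280, nearer to the 576 and 307 of the authors' value table.

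Mean intensities were corrected with limma's normexp method with an offset of 50 and normalised within each array by loess, with control spots at weight 0 and no step between arrays. Ratios of dim genes are drawn toward 0 by the offset. The design planned to use the well-above-background and outlier marks of another scanner format, which these files do not hold, so substitutes were computed. A spot was above background when its net signal exceeded the mean of the negative controls by 2.6 SD, and a probe when most of its spots were. Spots beyond the quartiles of their probe's 7 spots by more than about 1.4 interquartile ranges in either channel were left out, 6.47% to 8.77% per array. A gene was tested when its probe was above background in at least 1 channel on at least 3 arrays, which left out 462 genes. The brightest spot, controls included, read 29281, and no spot was left out for brightness. Where 1 channel was not above background on any array, the ratio is a bound, "at least N-fold", from the brighter channel's mean against the higher of the dim probe's own signal and the lowest signal of a probe above background, per channel after loess and Aquantile. Such bounds are open to dye bias.

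Ratios were tested against 0 with limma's lmFit and eBayes with an intercept only, with Benjamini-Hochberg adjustment over 5794 genes at 0.05. Symbols were matched by systematic name to a table of the R64 assembly, with 5756 of 6256 probes matched, and otherwise kept as systematic names. The files hold 1 probe per gene. Before the data were examined, 38 gene lists from textbook knowledge, the tests, the processing alternatives and the naming of genes were fixed. The genes to be named are the 12 highest and 12 lowest past the threshold with 1 sign on all 4 arrays, up to 4 members of largest ratio per list, up to 3 per arm or window past its test, and DUR3, ADH1, the marker genes and the mating-type genes whatever their value. Genes chosen after their values were seen are said to be so. The list symbols ARG5,6, ADE5,7 and DUR1,2 were not matched on the array. Lists with at least 5 tested members and chromosome arms were compared with all other genes by limma's camera, with a preset correlation of 0.01 and with an estimated correlation, and tested on their own by fry, adjusted over the lists or the arms. Arm and gene order were read from systematic names. Windows of 21 tested genes were set against 1000 shuffles of gene order over the genome. All 4 arrays share 1 slide, so no slide could be fitted as a batch.

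The procedure was tested on simulated arrays for this comparison. Spot intensities of 6065 genes were drawn with 199 genes changed and an array-to-array SD of 0.0718. It recovered 97.0% of 2-fold changes and 83% of changes of 0.5 on the log2 scale, and it called 0.0172% of unchanged genes. The median fitted ratio of genes raised 2-fold was 0.83. An arm shifted by 0.4 in the simulation had rank 1 among the arms, and 0 other arms passed. Both simulated channels were drawn from the D10 Small signal, with a dye difference shared by all genes. No dye effect of single genes and no error of the pool was put in, and few genes were changed. The rates hold for that setting and do not give the share of false calls on the real arrays.

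Alternatives covered no background correction, the scanner software's net ratio, median centring, Aquantile between arrays, no filter on dim probes, signal in both channels on all 4 arrays, all spots kept, array weights, the authors' value table, each array left out, a minimum fold of 1.2, the statistic without moderation, and windows of 11 and 41 genes. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 was used, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.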

Results

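Transcript levels were compared between the Saccharomyces cerevisiae translocant strain D10 Small and its parental strain WT San I on 4 two-colour oligonucleotide arrays. Each array held 1 of 4 biological replicates of D10 Small, labelled with Cy3, against the same pool of WT San I RNA, labelled with Cy5. Both strains were grown in YPD, a rich glucose medium, to an optical density of 0.4 to 0.5. D10 Small alone was grown with the aminoglycoside kanamycin at 200 mkg/ml, so strain and drug changed together. The dyes were not swapped, and the pool is 1 control sample, so its own spread is left out of every test. Each array carried 6256 gene probes with 7 spots each. The median raw spot intensity lay between 304 and 444 in the D10 Small channel and between 120.4 and 261 in the pool's channel. D10 Small gave signal above background for 91.8% to 93.2% of the probes and the pool for 86.0% to 89.1%. Ratios of the 4 arrays correlated with Pearson's r from 0.975 to 0.990 over genes, which are not independent replicates. The number of arrays limits the precision. All ratios below are D10 Small over pooled WT San I on the log2 scale, as mean ± SD over the 4 arrays.

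The transcriptomes of D10 Small and WT San I differed widely. D10 Small had far less transcript of the mitochondrial ATP synthase gene OLI1, of the serine deaminase gene CHA1 and of the asparaginase genes ASP3-1 to ASP3-4, and far more of the vitamin B6 gene SNZ1, the cell wall gene PIR3 and the mating gene STE6. Of 5794 genes tested, 2501 were higher and 2292 lower in D10 Small with limma at an adjusted p under 0.05, and 1001 did not pass. At least 2-fold differences were fewer, with 359 genes higher and 177 lower. The same sign was seen for 5030 genes on all 4 arrays, which share 1 pool and 1 dye orientation. The pool was not above background on any array for 129 of the higher genes, and D10 Small was not for 17 of the lower genes. Counts of 2-fold genes depended on the processing, with 538 higher and 280 lower without background correction. The authors' value table, whose normalisation is not stated, gave 576 and 307. The scanner software's net ratio gave 723 and 532, and with it 2253 genes were higher and 2530 lower at any fold. A test against a minimum fold of 1.2 left 1425 higher and 1151 lower. Of 173 named genes past the threshold, 32 had ratios over 1.5 times as large without background correction, 40 in the authors' value table and 55 with the scanner's net ratio, and 20 had ratios smaller by as much, or of opposite sign, with median centring.

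Among the 12 genes with the highest ratios in D10 Small, SNZ1 led with 5.0 ± 0.20 (SD, n = 4), a 32.0-fold difference. PIR3, a glycoprotein of the cell wall, followed with 4.71 ± 0.25. HSP26, a small heat shock protein, stood at 3.82 ± 0.18, and STE6, the exporter of the pheromone a-factor, at 3.65 ± 0.27. STE4, the beta subunit of the pheromone-coupled G protein, reached 3.38 ± 0.29. The secreted glycoprotein YGP1 reached 3.31 ± 0.09, the serine synthesis gene SER3 3.12 ± 0.10 and the vacuolar mannosidase AMS1 3.02 ± 0.29. The less characterised genes YER138W-A, ECM13, ARO5 and YBL107W-A lay at 3.92, 3.34, 3.26 and 3.09. Limma's adjusted p for these 12 genes ran from 1.21e-09 for YER138W-A to 9.60e-08 for ARO5.

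The lowest of all ratios belonged to OLI1, which encodes subunit 9 of the ATP synthase in the mitochondrial genome. OLI1 was bright in the pool and not above background in D10 Small, which makes it at least 125-fold lower, with a fitted ratio of -7.23 ± 0.20. CHA1, which degrades serine and threonine, had a ratio of -4.92 ± 0.27. The 4 ASP3 genes, near-identical copies for a secreted asparaginase on XII right, were not above background in D10 Small and at least 15.5-fold to 18.1-fold lower. Their probes cannot be taken as separate measurements. GSY2, the main glycogen synthase, stood at -3.88 ± 0.16. The leucine synthesis genes LEU2 and LEU1 had -3.20 ± 0.18 and -3.01 ± 0.11, the phosphate-response gene SPL2 had -3.01 ± 0.23, and the high-affinity hexose transporter HXT7 had -2.84 ± 0.46. AI5_ALPHA, an intron-encoded protein of mitochondrial COX1, was at least 5.08-fold lower. Limma's adjusted p for these 12 genes ran from 1.21e-09 for OLI1 to 7.57e-07 for HXT7.

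Of 38 gene lists fixed in advance, some were shifted in D10 Small and others held genes going both ways. Of the 37 lists with at least 5 tested members, 14 were higher and 7 lower in D10 Small by limma's camera test with a preset correlation of 0.01. None passed with an estimated correlation, where the adjusted p of all lists ran from 0.480 to 0.979. Fry called all 37 lists. It asks whether a list's genes moved one way on balance and does not compare them with other genes. The counts of members adjusted over the list alone were the same as those over all genes for every list except ergosterol synthesis, with 8 in place of 9 higher. The plot of list medians per array shows these shifts.

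**Figure D1:**
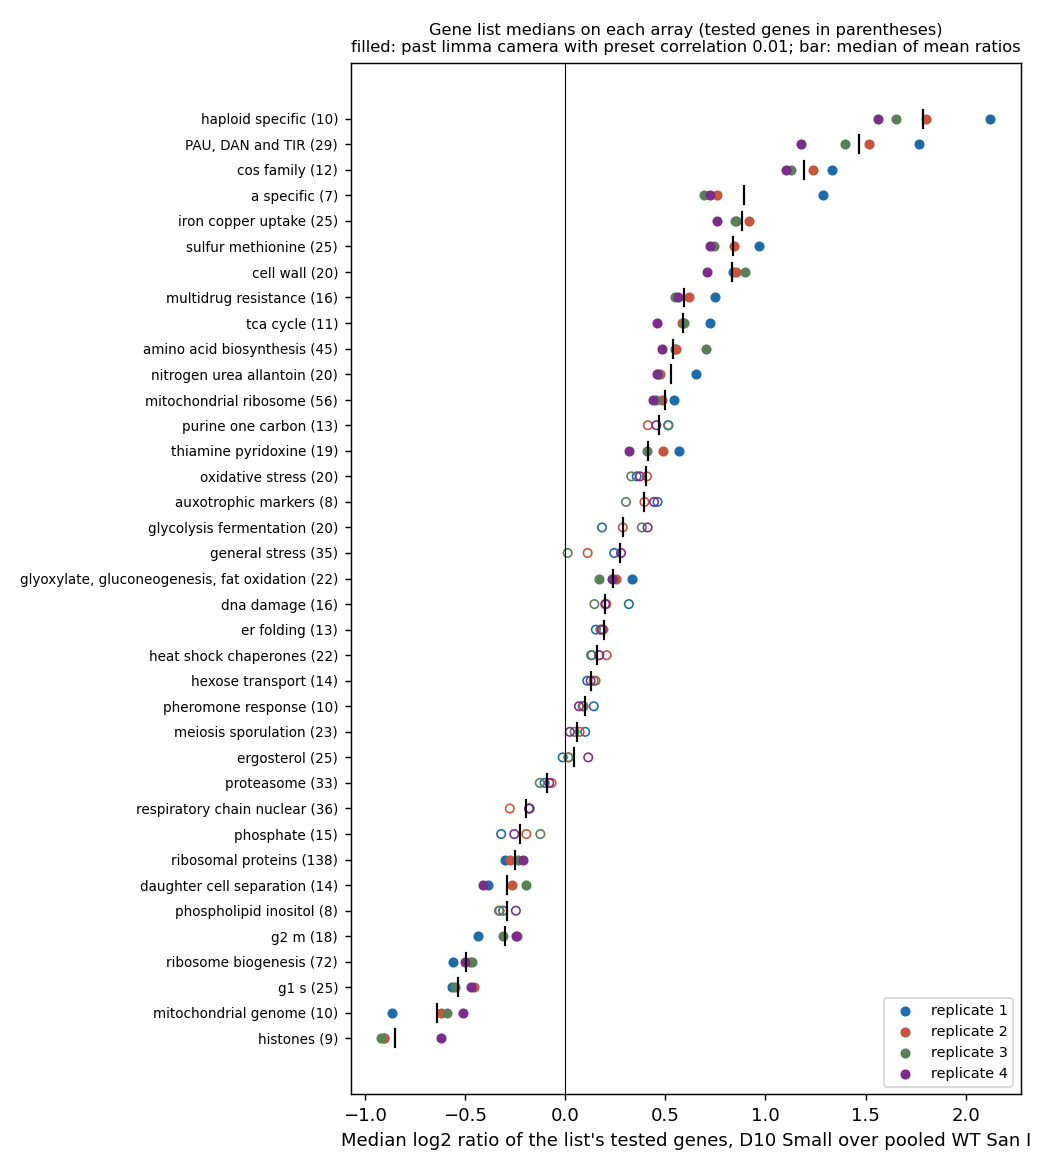
Each point is the median log2 ratio of a list's tested genes on 1 of the 4 arrays, D10 Small over pooled WT San I, with the number of tested genes in parentheses. Haploid-specific genes had the highest median (1.78) and histone genes the lowest (-0.85); filled points mark lists past limma's camera test with a preset correlation of 0.01.

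Haploid-specific and a-specific genes were higher in D10 Small. All 10 haploid-specific genes, which are repressed in a/alpha diploid cells, passed as higher, with a median of 1.78. Besides STE4, the G protein alpha subunit GPA1 had 3.01 ± 0.27 and the mating kinase FUS3 2.79 ± 0.33. The pool was not above background for AXL1, a processing protease of a-factor, which was at least 4.42-fold higher. RME1, a repressor of meiosis, had 1.99 ± 0.29, the scaffold STE5 1.58 ± 0.21, the G protein gamma subunit STE18 1.26 ± 0.16, and FAR1, NEJ1 and the mating-type switching endonuclease HO were at least 1.97-fold, 1.65-fold and 2.35-fold higher. All 7 a-specific genes also passed as higher, with a median of 0.89. The pool was not above background on any array for 4 genes of each list. These, and RME1, MFA1 and ASG7 with the pool above background on at most 2 arrays, entered the test through D10 Small alone. This favours positive ratios. STE6 led this list, and STE2, the receptor for alpha-factor, was at least 5.11-fold higher, BAR1 at least 1.88-fold and AGA2 at least 1.40-fold. Of the a-factor genes, MFA2 was at least 1.86-fold higher and MFA1 had 0.44 ± 0.10, and ASG7 had 0.32 ± 0.11. Limma camera gave an adjusted p of 0.000518 for the haploid-specific and 0.0101 for the a-specific list, and for both the adjusted p was 0.480 with an estimated correlation. With median centring in place of loess the a-specific list no longer passed, with an adjusted p of 0.0927 in limma camera against 0.00173 at the lowest over its alternatives, and neither AGA2 nor ASG7 passed. Without background correction and in the authors' value table the medians were 2.85 and 3.01 for the haploid-specific and 1.84 and 2.05 for the a-specific list, and with the scanner's net ratio the haploid-specific median was 4.76.

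Of the 4 alpha-specific genes, the alpha-factor genes MF(ALPHA)1 and MF(ALPHA)2 were not above background in D10 Small on any array and were not tested. SAG1, the alpha-agglutinin, had 0.44 ± 0.09 and the a-factor receptor STE3 0.27 ± 0.08 with loess, while STE3 had -0.14 with median centring. The pool was not above background for STE3, which leaves a bound of at least 1.2-fold. Pheromone-response genes gave no call as a list, with 5 of 10 higher and 4 lower. The mating transcription factor STE12 was higher with 0.97 ± 0.10, while its partner KAR4, on III left, was lower with -1.28 ± 0.11. The list median was 0.10 with loess and -0.28 with median centring, its mean was -0.03, and its limma camera adjusted p was 0.928.

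**Figure D2:**
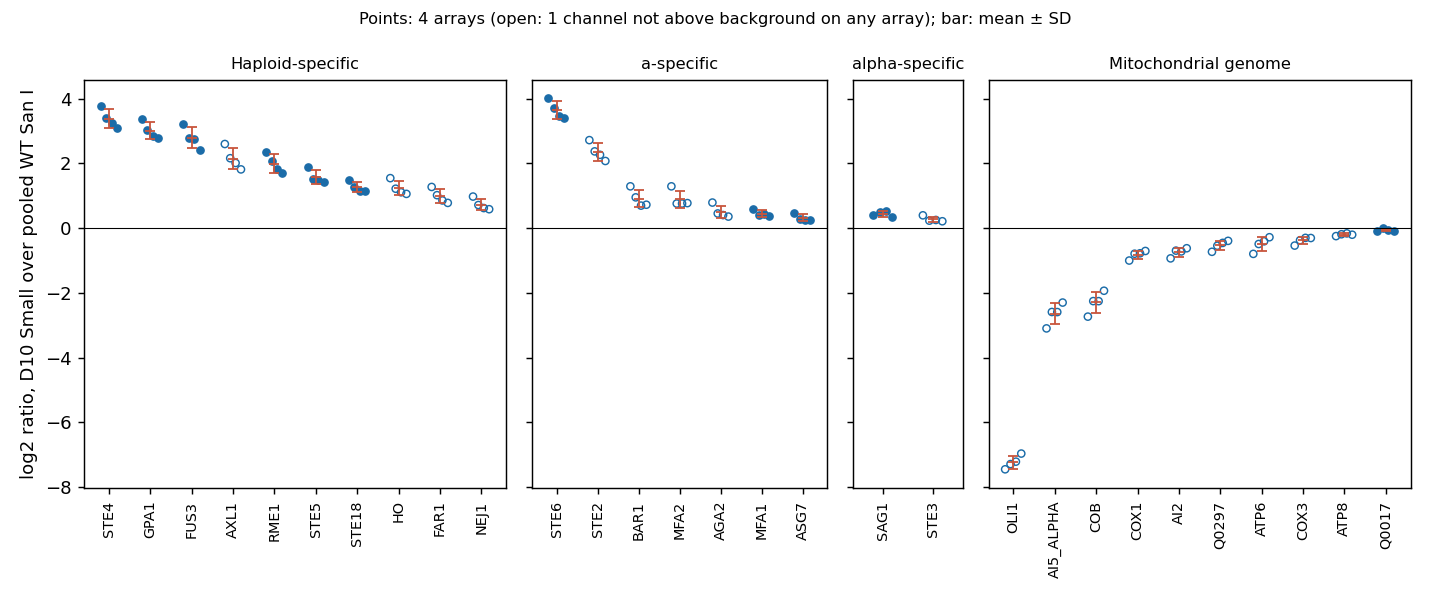
Log2 ratios of mating-type genes and mitochondrially encoded genes, D10 Small over pooled WT San I, with the 4 arrays as points and the mean ± SD as bars. Haploid-specific and a-specific genes lie above 0 on all 4 arrays, from 0.32 for ASG7 to 3.65 for STE6, and OLI1 lies at -7.23; open points mark genes whose dimmer channel was not above background on any array, and STE3 turned to -0.14 with median centring.

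Transcripts of the mitochondrial genome were lower or not measurable in D10 Small. Of its 23 genes on the array, 10 were tested, and 9 of these were lower with a median of -0.64. All 9 were not above background in D10 Small on any array and were above it in the pool on at least 3 arrays, so they entered the test through the pool alone, which favours negative ratios. Q0017, the other tested gene, had -0.06 ± 0.04 and did not pass. Besides OLI1 and AI5_ALPHA, the cytochrome b gene COB was at least 4.14-fold and the cytochrome oxidase gene COX1 at least 1.67-fold lower. With the dim genes set at their bounds the median was -0.58. The other 13 mitochondrial genes, COX2 and VAR1 among them, were not above background in D10 Small and too dim in the pool to be tested. Limma camera gave an adjusted p of 0.00103, and the adjusted p was 0.480 with an estimated correlation. The median depended on the processing, from -0.12 without the filter on dim probes to -1.80 in the authors' value table.

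Nuclear genes for mitochondrial proteins went different ways in D10 Small. Of 56 genes of the mitochondrial ribosome, 44 were higher and 6 lower, with a median of 0.50 and examples in MRPS16 (1.44 ± 0.18) and MRP51 (1.19 ± 0.13). Genes of the tricarboxylic acid cycle were higher for 8 of 11 members and lower for 2. The isocitrate dehydrogenase subunits IDH2 and IDH1 had 2.79 ± 0.04 and 2.73 ± 0.05, aconitase ACO1 had 2.52 ± 0.08 and citrate synthase CIT1 had 1.16 ± 0.11, or 0.59 with median centring. Limma camera adjusted p was 2.40e-05 and 0.0259 for these 2 lists, and for both the adjusted p was 0.480 with an estimated correlation. With median centring the tricarboxylic acid list had an adjusted p of 0.0617 in limma camera, against 0.0204 at the lowest over its alternatives. Nuclear respiratory chain genes were lower for 20 of 36 members and higher for 9, with ATP5 at -0.98 ± 0.12 and ATP2 at -0.94 ± 0.05 against CYC7 at 1.06 ± 0.08. This list missed the threshold with a limma camera adjusted p of 0.0574, and it passed without replicate 1 with a median of -0.20 and an adjusted p of 0.0302, the range over its alternatives being 0.0302 to 0.121. It also passed without background correction, in the authors' value table and without I left, III, VII right and XV left. The list for the glyoxylate cycle, gluconeogenesis and fatty acid oxidation had 15 of 22 members higher and 1 lower, with a median of 0.24, which was 0.86 with the scanner's net ratio. Its leading members YAT1 (1.83 ± 0.27) and CRC1 (1.09 ± 0.21) act in carnitine-dependent transport, beside PCK1 (0.82 ± 0.17) of gluconeogenesis. Its limma camera adjusted p was 0.00804, and 0.480 with an estimated correlation, and with median centring the adjusted p was 0.645 against 0.000931 at the lowest.

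Subtelomeric and cell wall gene families were higher in D10 Small. Of 29 tested PAU, DAN and TIR genes, a family of cell wall mannoproteins induced by anaerobic growth, 28 were higher and 1 lower with a median of 1.47, which was 2.33 with the scanner's net ratio. PAU12 had 1.85 ± 0.20 and PAU2 1.80 ± 0.20. All 12 genes on the COS list were higher with a median of 1.19, led by COS8 with 1.76 ± 0.14 and COS1 with 1.62 ± 0.05. The COS list was drawn by symbol and also holds COS111, which is not of this family. Members of both families are near-identical and may share signal, so their counts are not independent. Cell wall stress genes were higher for 16 of 20 members and lower for 2, with a median of 0.84. PIR3 was followed by PRM5 with 2.37 ± 0.15, the glucan synthase GSC2 with 2.28 ± 0.19 and the mannosyltransferase KTR2 with 1.52 ± 0.14. Limma camera adjusted p was 8.53e-07 for the PAU, DAN and TIR list, 7.13e-05 for COS and 0.000791 for the cell wall list, and for each the adjusted p was 0.480 with an estimated correlation. With median centring the cell wall list had a median of 0.50 and an adjusted p of 0.0692 in limma camera, against 0.000490 at the lowest over its alternatives.

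Lists for amino acid, sulfur and vitamin synthesis, for iron and copper uptake and for nitrogen use held more higher than lower genes in D10 Small, and all but the thiamine list had lower members too. Of 45 amino acid synthesis genes, 33 were higher and 9 lower, with a median of 0.54. SER3, the arginine gene ARG1 (2.96 ± 0.07) and the lysine gene LYS1 (2.33 ± 0.11) stood against LEU1. Sulfur and methionine genes were higher for 18 of 25 members and lower for 5, with MET5 at 1.82 ± 0.11, STR3 at 1.67 ± 0.21 and MET17 at 1.63 ± 0.10, or 1.0 with median centring. Iron and copper uptake genes were higher for 17 of 25 members and lower for 4, with the mannoprotein FIT3 at 2.53 ± 0.13, the mRNA-decay factor TIS11 at 2.31 ± 0.12 and the siderophore transporter ARN1 at 2.26 ± 0.16. Nitrogen, urea and allantoin genes were higher for 16 of 20 members and lower for 3, with the urea transporter DUR3 at 1.52 ± 0.21, the arginase CAR1 at 1.08 ± 0.16 and the amino acid permease AGP1 at -1.13 ± 0.13. Thiamine and pyridoxine genes were higher for 15 of 19 members and lower for 0, with SNZ3 at least 2.75-fold and SNZ2 at least 2.40-fold higher and THI20 at 1.15 ± 0.14. Limma camera adjusted p was 0.000833 for amino acids, 0.0145 for sulfur, 0.000688 for iron and copper, 0.0145 for nitrogen and 0.00208 for thiamine, and for each the adjusted p was 0.480 with an estimated correlation. With median centring limma camera's adjusted p was 0.121 for amino acids, 0.121 for thiamine and 0.185 for nitrogen, against 0.000555, 0.000139 and 0.00442 at the lowest over their alternatives. Purine and one-carbon genes, with 9 of 13 higher and 3 lower, had a limma camera adjusted p of 0.0733, which was 0.0241 without I left, III, VII right and XV left, in a range of 0.0241 to 0.129 over its alternatives. The glycine cleavage gene GCV1 had 1.70 ± 0.11 and ADE6 -1.17 ± 0.07. ARG1 and THI20 lie on XV left, AGP1 on III left and ADE6 on VII right, arms described below.

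Multidrug resistance genes were higher for 12 of 16 members and lower for 3, with a median of 0.59, which was 0.96 with the scanner's net ratio and in the authors' value table. The drug efflux pump PDR5 had 2.68 ± 0.10 and the polyamine exporter TPO1 1.25 ± 0.09, while TPO4 had -1.24 ± 0.04. The limma camera adjusted p was 0.0279, and the adjusted p was 0.480 with an estimated correlation.

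Ribosome, DNA replication and cell division genes were lower in D10 Small. Of 72 ribosome biogenesis genes, 61 were lower and 7 higher, with a median of -0.49. KRR1 had -2.06 ± 0.10, ENP2 -1.98 ± 0.09, SPB1 -1.61 ± 0.13 and NOP7 -1.55 ± 0.09, and these 4 genes lie on III left or VII right, the arms described below. Of 138 genes on the ribosomal protein list, 96 were lower and 20 higher with a median of -0.25, or -0.66 with median centring, RPS0A at -1.30 ± 0.19 and, in the other direction, RPS14B at 2.27 ± 0.08. This list was drawn by symbol and also holds RPP1, a subunit of RNase P and not a ribosomal protein, which was lower with -0.37 ± 0.09. Genes expressed at the start of S phase were lower for 23 of 25 members and higher for 0, with the replication protein RFA1 at -1.44 ± 0.10 and the cohesin subunit MCD1 at -1.35 ± 0.05. Histone genes were lower for 8 of 9 members and higher for 1, with HTB1 at -1.51 ± 0.09 and HTA1 at -1.07 ± 0.07. Genes of the G2 and M phases were lower for 14 of 18 members and higher for 3, with HOF1 at -0.91 ± 0.05 and the cyclin CLB1 at -0.76 ± 0.07. Genes of daughter cell separation were lower for 11 of 14 members and higher for 2, with DSE3 at -1.16 ± 0.08 and BUD9 at -1.15 ± 0.10. RPS0A, CLB1 and BUD9 also lie on VII right. RFA1, on I right, lies within a lower window of chromosome I, from YAL014C to YAR018C, with a median of -0.68. Limma camera adjusted p was 1.37e-08 for ribosome biogenesis, 1.24e-05 for ribosomal proteins, 7.38e-06 for S phase, 0.00649 for histones, 0.0101 for G2 and M, and 0.0220 for daughter separation, and for each the adjusted p was 0.480 with an estimated correlation. With median centring the last 2 of these lists had 0.145 and 0.0872 in limma camera, against adjusted p of 0.00715 and 0.0139 at the lowest over their alternatives.

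Carbon and phosphate genes held large differences in both directions and gave no list call. Among hexose transporters, the high-affinity HXT7 and HXT6 (-2.63 ± 0.36), which are near-identical copies, were lower, and the low-affinity HXT3 (2.5 ± 0.08) and HXT1 (1.74 ± 0.25) were higher. Over this list 9 of 14 genes were higher and 3 lower, with a limma camera adjusted p of 0.239 and a median of 0.13 that turned to -0.31 with median centring. In the phosphate list, 9 of 15 genes were lower and 4 higher, with SPL2, the polyphosphate genes VTC3 (-2.37 ± 0.10) and VTC4 (-1.95 ± 0.18) and the transporter PHO84 (-2.21 ± 0.12) lowest. Its adjusted p was 0.0700 in limma camera, and with median centring the list passed as lower with a median of -0.57 and an adjusted p of 0.0434, the range over its alternatives being 0.0434 to 0.116. Glycolysis and fermentation genes were higher for 13 of 20 members and lower for 6, with a median of 0.29 that turned to -0.38 with median centring. CDC19, the pyruvate kinase on I left, had -1.30 ± 0.14, the phosphoglycerate kinase PGK1 on III right -0.82 ± 0.07, and TDH2 1.24 ± 0.10, which became -2.16, -1.77 and 0.79 with median centring. The list's limma camera adjusted p was 0.239, and with median centring 0.0116, the range over its alternatives being 0.0116 to 0.415. Without I left, III, VII right and XV left the glycolysis list passed as higher with a median of 0.60 and an adjusted p of 0.0475 in limma camera.

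Stress genes split within D10 Small. General stress genes were higher for 18 of 35 members and lower for 16, with GSY2 lowest and HSP26, YGP1 and HSP12 (2.56 ± 0.18) highest, and the list had a limma camera adjusted p of 0.928. The medians of the general stress and oxidative stress lists, 0.27 and 0.40, turned to -0.04 and -0.09 with median centring. Heat shock chaperones were higher for 12 of 22 members and lower for 8 (adjusted p of 0.386 in limma camera), with SSA4 at 2.24 ± 0.08 and the mitochondrial chaperonin HSP60 at 1.35 ± 0.07. Oxidative stress genes were higher for 12 of 20 and lower for 8 (0.465), with ATR1 at 1.5 ± 0.10 and the thioredoxin TRX2, on VII right, at -1.12 ± 0.11. DNA damage genes were higher for 9 of 16 and lower for 5 (0.323), with RNR2 at 0.78 ± 0.12 and DUN1 at -0.72 ± 0.12. With median centring HSP60 had 0.47 and RNR2 0.14. Endoplasmic reticulum folding genes were higher for 7 of 13 and lower for 3 (0.247), with PDI1, on III left, at -1.24 ± 0.15. Proteasome genes were lower for 17 of 33 and higher for 10 (0.239), with PUP2 on VII right at -0.97 ± 0.03 and PRE6 on XV left at 0.70 ± 0.06, or 0.36 with median centring. With median centring the proteasome list passed as lower, with a median of -0.28 and a limma camera adjusted p of 0.0116 in a range of 0.0116 to 0.312 over its alternatives. Ergosterol genes were higher for 9 of 25 and lower for 10 (0.856), with ERG3 at 1.38 ± 0.05. Phospholipid genes were lower for 6 of 8 and higher for 2 (0.143), with CHO2 on VII right at -1.64 ± 0.12 and OPI3 at 1.37 ± 0.10. Meiosis genes were higher for 11 of 23 and lower for 3, with a median of 0.06 that turned to -0.30 with median centring, and a limma camera adjusted p of 0.314 that became 0.00971, in a range of 0.00971 to 0.667 over its alternatives. Values in parentheses after the counts of this paragraph are limma camera adjusted p.

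Marker genes that laboratory strains often carry as mutant alleles were read in D10 Small because constructed strains often carry them. LEU2 was lower, MET17 and HIS3 (1.12 ± 0.08) were higher, and LYS2 had 0.74 ± 0.02, URA3 0.48 ± 0.11 (0.81 in the authors' value table), ADE2 0.31 ± 0.12 and ADE1 -0.25 ± 0.06. With median centring ADE1 had -0.06 and did not pass. TRP1 did not pass, with 0.10 ± 0.13 and a limma adjusted p of 0.0855, and it passed with median centring (limma adjusted p of 0.00384, in a range of 0.00384 to 1 over its alternatives), without background correction, with array weights and in the authors' value table. As a list, 5 of 8 were higher and 2 lower, with a limma camera adjusted p of 0.239.

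Whole stretches of chromosomes differed in D10 Small. The left arm of chromosome III had the lowest median of the 32 arms, -0.80, with 44 of 54 genes lower and 4 higher. CHA1, LEU2 and KRR1 had its largest ratios. The left arm of I stood at -0.52, with 48 of 64 genes lower, among them the translation factors EFB1 (-1.96 ± 0.10) and FUN12 (-1.51 ± 0.11), against PAU8 at 1.70 ± 0.16 near the telomere. The right arm of VII stood at -0.48, with 207 of 272 genes lower, TNA1 at -2.22 ± 0.07 among them, while GSC2 and RME1 on the same arm were higher. III right had a median of -0.31, with 62 of 96 genes lower, among them RBP95 at -1.70 ± 0.14. On XV left, 109 of 158 genes were higher with a median of 0.45, led by ARG1, DDR2 (2.07 ± 0.39) and MDM38 (2.01 ± 0.14), and on VIII left 31 of 46 were higher with a median of 0.31, led by VMR1 at 2.30 ± 0.06. The array medians of an arm differed little, with SD from 0.01 to 0.05 for these 6 arms. With the scanner's net ratio the medians of I left, III left, III right, VII right and VIII left were -0.80, -1.35, -0.60, -0.83 and 0.49.

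By limma camera with a preset correlation, 6 arms were lower and 11 higher in D10 Small. The adjusted p was 2.40e-09 for III left, 3.62e-07 for I left, 3.76e-12 for VII right, 1.77e-05 for III right, 1.77e-05 for XV left and 0.00164 for VIII left in limma camera. No arm passed with an estimated correlation, where the adjusted p of limma camera was 0.273 for III left and III right, 0.366 for I left, and 0.377 for VII right, XV left and VIII left. The other lower arms, IV left and IV right, had medians of -0.13 and -0.10, and the other higher arms, II left, II right, VI left, VII left, IX right, XI left, XV right, XVI left and XVI right, had medians from 0.11 to 0.27. With median centring IV left, IV right, VI left, VII left and IX right no longer passed, with limma camera adjusted p of 0.0937, 0.25, 0.371, 0.115 and 0.0545, each the highest over its alternatives, which began at 0.00657, 0.00616, 0.0153, 0.0125 and 0.00442. Without the genes of I left, III, VII right and XV left, 83 of the remaining genes were lower by at least 2-fold in place of 177, a comparison added after the data were examined. In that setting 6 arms were higher and 2 lower. VI left, VII left, XV right and XVI left no longer passed there, with limma camera adjusted p of 0.0722, 0.0658, 0.0707 and 0.0549, the last 2 being the highest over their alternatives, which began at 0.0123 and 0.010.

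Windows of 21 consecutive tested genes placed these shifts along the chromosomes. Of 5464 windows, 206 had a median below -0.53 and 42 a median above 0.65. These limits hold the lowest and the highest window of 95% of 1000 shuffles of gene order. The lower windows lay on I, III and VII alone. The lowest was centred on KAR4 on III left with -1.24, and those of VII ran from YGR079W to SCW4, with -0.78 at the lowest, around TWF1. The 42 higher windows all lay on XV left, between INP54 and DIS3, with a highest median of 1.09 around APM4. Genes are not independent replicates, and 0.000999 is the smallest p that 1000 shuffles can give. Median centring gave 131 lower windows. Window counts moved with the window length, to 6 higher and 37 lower for 11 genes and to 60 higher and 343 lower for 41 genes.

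**Figure D3:**
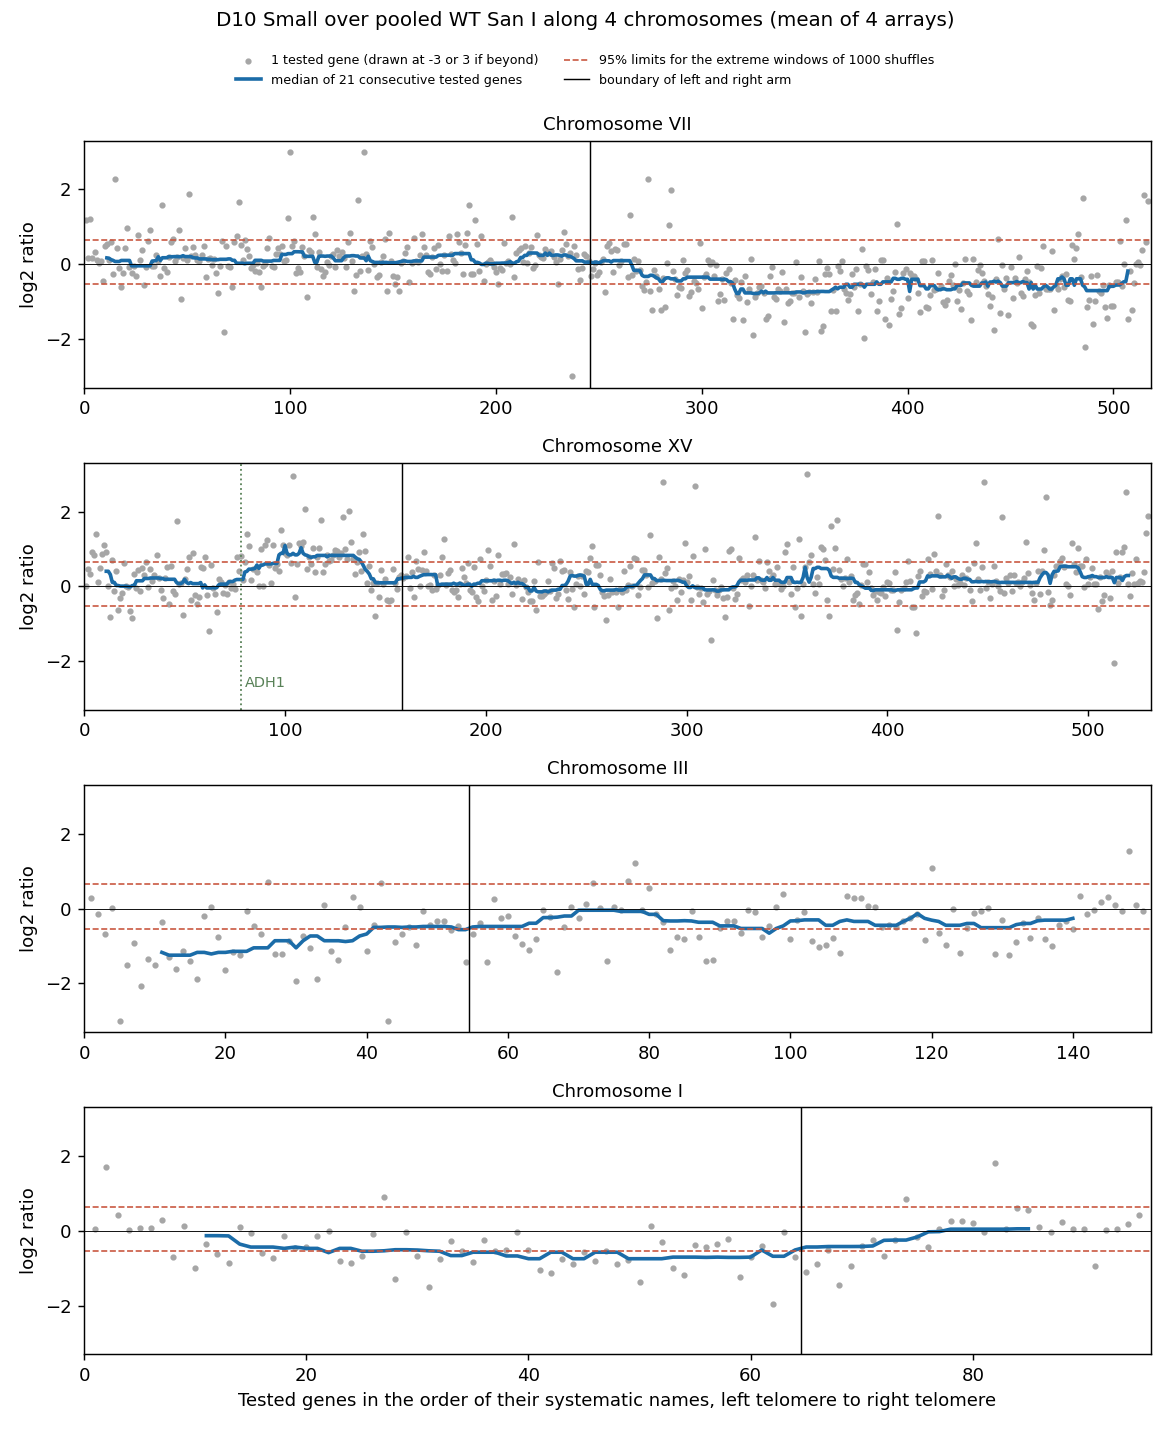
Log2 ratio of each tested gene (grey) and the median of 21 consecutive genes (blue) along chromosomes VII, XV, III and I, D10 Small over pooled WT San I, with genes in the order of their systematic names. Dashed lines at -0.53 and 0.65 are the 95% limits for the lowest and highest windows of 1000 shuffles; the median falls to -0.78 on VII right and -1.24 on III left and reaches 1.09 on XV left, beyond ADH1.

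The neighbourhoods of DUR3 on VIII left and ADH1 on XV left were read as loci fixed in advance. The labels give no junction for D10 Small, and neither gene is known here to lie at one. DUR3 had 1.52 ± 0.21, or 2.44 with the scanner's net ratio. Of the 10 tested genes on its telomere side 7 were higher and 0 lower with a median of 0.37, the chromatin-remodelling gene SNF6 leading with 1.73 ± 0.08. Of the 10 on its centromere side 3 were higher and 4 lower with a median of -0.05. ADH1, the main alcohol dehydrogenase of fermentation, had 0.81 ± 0.08 with loess but -0.14 with median centring, where its limma adjusted p was 0.0249, the highest over its alternatives against 6.97e-09 at the lowest. On its centromere side 9 of 10 genes were higher and 0 lower with a median of 0.46, including ATG19 with 1.40 ± 0.07 and IRA2 with 1.08 ± 0.07. On its telomere side 4 were higher and 2 lower with a median of 0.05. The difference between the sides was not tested, and SNF6, ATG19 and IRA2 were chosen after their values were seen. Files and labels name no genome build, so chromosome, arm and order come from systematic gene names and no coordinates are given.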

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

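The sets of 4 arrays in this part are the gene lists, the chromosome arms and the named genes. Many of these genes were named for their large ratios past the threshold, by the rule fixed in advance. A single array stood apart from the other 3 by Dixon's criterion in 16 of 244 sets of 4 arrays, where chance alone gives about 1 in 20, or 12.2. The array apart was replicate 1 in 8 of these and replicate 4 in 6, and the log2 ratios over all tested genes spread most on replicate 1 (SD of 0.716) and least on replicate 4 (0.603).

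On replicate 1, the a-specific list had a median of 1.29 against 0.72 for the other arrays, and the a-factor gene MFA2 had 1.29 against 0.76. MFA2 was the median gene of that list on replicate 1, so both flags rest on the same value. The nitrogen, urea and allantoin list had 0.65 against 0.47. The daughter-specific gene DSE3 had -1.28 against -1.11, the polo kinase CDC5 -0.87 against -0.64, the linker histone HHO1 -1.04 against -0.94, the hexose transporter HXT3 2.37 against 2.54 and the isocitrate dehydrogenase IDH1 2.81 against 2.70.

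On replicate 4, the histone list had a median of -0.62 against -0.90 and the arm XVI left 0.13 against 0.16. HSP26 had 4.09 against 3.73, the siderophore transporter ARN1 2.02 against 2.32, the thioredoxin TRX2 -0.96 against -1.17 and the ribosome biogenesis gene NOP7 -1.68 against -1.50. On replicate 2, the nuclear respiratory chain list had -0.28 against -0.18, and on replicate 3 the one-carbon gene MTD1 had 0.91 against 1.07. The direction was the same on all 4 arrays for each of these 16 values. For the genes among them, naming by large ratios past the threshold favours this.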

How the results depend on the processing

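The settings without I left, III, VII right and XV left and without the PAU, DAN, TIR and COS families were chosen after the data were examined. Outside the arrays left out, 383 of the values for gene lists kept their side of the threshold, 7 gained a call, 9 lost it and 2 reversed. Reversed means a change of sign with a call in the main or the alternative setting. Values without a call in either setting count as kept even where their sign changed. For arms 335 kept their side, 2 gained a call and 10 lost it. Some arms without a call turned sign, such as I right, with 0.04 in the main setting and -0.22 at the lowest. For named genes 2183 kept their side, 4 gained a call, 9 lost it and 2 reversed. With median centring ADH1 turned to -0.14, STE3 to -0.14, the glycolysis list to -0.38 and the meiosis list to -0.30, the a-specific list had a median of 0.85 without passing, 7 in place of 14 lists were higher, and 131 windows were lower. The cause was not tested, apart from the step itself, which leaves brightness-dependent dye differences in place. Of 4793 calls, 3713 remained under median centring with the same sign and 176 passed with the opposite sign. Median centring moved the median of all genes by 0.04 and the scanner's net ratio by -0.06.

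The count of genes at least 2-fold higher was 723 with the scanner's net ratio and 576 in the authors' value table. The count of those at least 2-fold lower was 532 and 307 in the same settings and 280 without background correction, settings without the offset of 50 or of unstated construction. A minimum fold of 1.2 left 1425 genes higher and 1151 lower. Without I left, III, VII right and XV left, 83 genes were lower by at least 2-fold and 6 arms were higher and 2 lower. XV left was not tested there, and VI left, VII left, XV right and XVI left lost their calls. Camera compares an arm with all other tested genes, and the median of all genes rose by 0.02 in that setting. Calls of slightly higher arms are thus partly relative to the lowered arms, and no further cause was tested. Of 21 lists past the threshold, 7 had medians over 1.5 times as large without background correction and 7 in the authors' value table, and of 17 arms 8 did so with the scanner's net ratio. Windows of 11 genes gave 6 higher and 37 lower, and windows of 41 genes 343 lower. Leaving out each array in turn gave 2307 to 2450 genes higher and 2114 to 2253 lower, and 1 list, the nuclear respiratory chain, gained a call without replicate 1. Without each array in turn the haploid-specific median was 1.67 to 1.86, the a-specific 0.76 to 0.94, the mitochondrial genome -0.68 to -0.57, III left -0.81 to -0.78, VII right -0.50 to -0.47 and XV left 0.42 to 0.46.

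Aquantile left every ratio as it was, so it says nothing about stability. The brightest-probe alternative is void with 1 probe per gene, and the adjustment for probe base composition was not run because probe sequences were not used here. No paired analysis was possible because there is only 1 group. Low signal in the pool limits 129 higher genes to bounds.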

Other observations

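The tests of nuclear mitochondrial ribosome genes, of alpha cells, of chromosome III and of copy number, and the search for chromosome segments, were chosen only after the results they bear on were seen. Genes without signal in D10 Small clustered in 2 places. Of the 17 lower genes not above background in D10 Small on any array, 9 belong to the mitochondrial genome and 7 to the ASP3 locus on XII right, with PHM6 left over. The ASP3 copies are near-identical and cannot be taken as separate measurements, so the 7 are not independent. At this locus the ORFs YLR156W, YLR159W and YLR161W, which by their names lie among or next to the ASP3 copies, were at least 1.33-fold, 1.32-fold and 1.38-fold lower beside ASP3-1 to ASP3-4. The retrograde genes DLD3, PYC1, PDH1 and ATO3, named before their values were seen, had 1.21 ± 0.05, 1.59 ± 0.09, 1.55 ± 0.10 and 0.18 ± 0.06. The ORFs of the ASP3 locus and PHM6 were chosen after their values were seen.

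A search for the best single stretch on each chromosome, leaving out 10 tested genes at each end, placed edges near both loci fixed in advance. On XV it ran from DUF1, 2 tested genes on the telomere side of ADH1, to TOS7, with 65 genes at a median of 0.79 against 0.10 for the other searched genes, 62 genes higher and 1 lower. On VIII the search divided the chromosome between DUR3 and its neighbour RPS20, with 0.49 outside against -0.06 inside the stretch from RPS20 to BAT1. On VII the stretch from TIM21 to CWC22 held 228 genes with a median of -0.62 against 0.12, 189 lower and 22 higher. The shuffle p, adjusted over 16 chromosomes, was 0.00798 for VII and XV, from the smallest p that 500 shuffles can give, and 0.0160 for VIII. I and XII (0.00798), VI (0.0160) and V (0.0274) also passed, and III did not (0.0674). The stretch on XII, from ACS2 to YLR162W, holds the ASP3 copies, so its 10 genes are not independent. Resampled edges left the start on VII between YGR026W and YGR041W and that on XV between YOL098C and YOL082W, while on VIII the edge was loose, between YHL025W and YHR008C.

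Lower mitochondrial transcripts in D10 Small came with higher nuclear retrograde genes. The list's median of -0.64 lay at percentile 0 of 10000 lists matched on pool brightness, but 9 of its 10 genes passed the filter through the pool alone, which favours a negative sign, so an effect of dim signal or dye cannot be told apart for the list. A fall of all transcripts for mitochondrial proteins is argued against by the mitochondrial ribosome list, whose lowest array median was 0.44, but the nuclear respiratory chain list had a median of -0.19 with 20 of 36 genes lower, and a fall limited to respiratory genes stays open. Retrograde genes, which rise in cells without mitochondrial DNA, had a median of 1.38 over DLD3, ATO3, PYC1 and PDH1, although ATO3 had only 0.18. CIT2, another retrograde gene, chosen after its value was seen, had only 0.25 ± 0.21. The median goes with loss of the mitochondrial genome or of its transcription, while ATO3 and CIT2 hardly do. Among the mitochondrial genes Q0017 alone was above background in D10 Small, on all 4 arrays. Its ratio of -0.06 ± 0.04 is not explained by such a loss. No DNA was measured, and a translational effect of kanamycin on mitochondria, which only D10 Small received, stays open and untested beside the strain.

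Haploid-specific genes were higher, as in cells without a1-alpha2 repression, and a-specific genes with them, which loss of that repression alone does not give. The median of both lists, 1.26, lay at percentile 100 of 10000 matched lists. The pool was not above background on any array for 4 genes of each list, which passed the filter through D10 Small alone. That favours a positive sign, so an effect of dim signal or dye cannot be told apart by this test. With signal in both channels on all 4 arrays the haploid-specific list still passed, with a median of 2.79 and a limma camera adjusted p of 0.00672. Dye effects of single genes stay open without a dye swap. Alpha-type haploid cells, which repress a-specific genes, are argued against as the source of the a-specific part. Its lowest array median was 0.69, a sign that the filter favours, while STE6, with signal in both channels on all 4 arrays, had 3.65 ± 0.27. The median of the a-specific list was 0.85 with median centring, where it no longer passed. As a source of the haploid-specific genes alpha-type cells cannot be told apart. MF(ALPHA)1 was above background on 0 arrays in D10 Small and on only 1 in the pool, which leaves its probe untested. SAG1 and STE3 had 0.44 and, with loess but not with median centring (-0.14), 0.27. Loss of a chromosome III copy with MATalpha may be involved, but the median of III right, -0.31, ran over the alternatives from -0.24 to -0.60. Only the scanner's net ratio, with -0.60, was past the level of a loss of 1 copy in 3. For III right no setting came near -1, the level of 1 copy over 2. III left had -0.80, so the arms differed in the main setting. Its median was -0.56 without the filter on dim probes, -0.98 without background correction, -1.06 in the authors' value table and -1.35 with the scanner's net ratio. The main ratios are drawn toward 0 by the offset, and simulated genes raised 2-fold had a median fitted ratio of 0.83. Loss of a chromosome III copy cannot be told apart from other causes without DNA or a known ploidy.

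The shifts on I, III, VII and XV may reflect copy number in the translocant, a hypothesis found and tested on the same data. The medians of I left, III left, VII right and XV left lay 0 percent from the nearer end of 10000 brightness-matched lists. That test cannot decide on brightness, because loess had already removed trends with brightness and the arms were taken up for their shift. Genes outside the fixed lists kept 92.1% or more of each arm's median, with -0.51, -0.74, -0.50 and 0.43. They were 57 of 64, 42 of 54, 222 of 272 and 136 of 158 genes, so leaving out list members could move these medians little. In the stretches of VII and XV at least 86.4% of the genes lay on the stretch's side of 0, and on I and III at least 86.3% of the searched genes outside the least lowered stretch lay below 0, but the search itself favours both shares. On all 4 chromosomes copy number cannot be told apart from regional regulation, because no DNA was measured. A ratio of 3 copies over 2 would be 0.58 and of 1 over 2 would be -1, but the medians moved with the processing, that of III left from -0.80 to -1.35 with the scanner's net ratio, and ploidy is not given in the sources used here.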
